A study of Mus musculus with 8 samples.

How the data were processed

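Whole B16F1 tumours from 4 groups (WT or TNFR KO hosts, untreated or 5 h after 20 Gy) were profiled on 8 Affymetrix mouse whole-genome arrays. Per the labels, cells were injected into 5 to 7 mice of each host, tumours had grown to between 268 and 478 cubic mm, RNA was pooled by group, and 6 µg of total RNA was labelled for each pool, which was measured in duplicate. The deposited values are MAS5 signal intensity on a linear scale, MAS5 being named in the submitters' processing notes without a version. The 2%-trimmed mean was 500.00 on every array, so the authors had scaled each array to a common target. Every probe set had a value on every array. The number of arrays limits the precision of every value.

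Signals were transformed as log2(signal + 16), so log2 differences of genes with a dim pool depend on that pseudocount. Gene symbols came from the array annotation supplied with the data: 34958 probe sets named 1 gene, 932 several and 9160 none, and 64 were controls. Of the first, 34754 were found by gene identifier in a separate table of mouse genes, and 0 symbols had to be changed. Each of 18193 genes was represented by its brightest probe set naming that gene alone, and 11345 genes whose mean log2 signal reached the median of all non-control probe sets (6.41, a signal of 68.8) were tested.

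Analyses used R 4.3.3 and limma 3.58.1, with figures in matplotlib 3.10.9. Because duplicates are technical, effects of host and of radiation over both levels of the other factor were fitted on the 4 pool means with an additive model (1 residual degree of freedom, 9.52 prior degrees of freedom), calling genes at a Benjamini-Hochberg adjusted p under 0.05. With 1 pool per group, that residual is the difference between the radiation effects of the 2 hosts. The error of these fits therefore holds any real difference of that kind, and no spread between replicate pools or animals. Each single-pool comparison, and the difference between the radiation effects, was fitted on the 8 arrays as 4 group means (4 residual degrees of freedom) and also required a 2-fold difference. Calls shared by comparisons with no pool in common were counted against the product of their call rates. All tests were two-sided.

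Before the data were examined, 28 gene lists with 507 symbols were fixed, of which 468 were matched to the array, with some genes in more than 1 list. They covered the targeted receptors, TNF and NF-kB targets, interferon response, antigen presentation, p53 targets, mitosis, DNA replication, DNA repair, hypoxia and glycolysis, angiogenic factors, immediate-early genes, heat shock and unfolded protein response, and apoptosis. Markers of macrophages, lymphocytes, neutrophils, endothelium, fibroblasts and matrix, smooth muscle and pericytes, skeletal muscle, keratinocytes, adipocytes, erythroid cells and melanocytes were also listed. Further lists held genes neighbouring Tnfrsf1a and Tnfrsf1b, genes that differ between 129 and C57BL/6 mice, and sex-linked genes. The 21 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with the estimated correlation as the alternative. That estimate rests on 1 residual degree of freedom between pools for host and for radiation, and on duplicate arrays of the same RNA for the difference between radiation effects, where it holds no variation between pools.

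The genes named were also set beforehand by rule. They were Tnfrsf1a, Tnfrsf1b, Tnf, Cdkn1a, Mdm2 and Ccng1; the 12 highest and 12 lowest called differences of each pool-level effect; the 5 highest and 5 lowest of each single-pool comparison and of the difference between radiation effects; and up to 4 called members of each list. Of these, the genes printed were chosen after values were seen, with preference in the host comparison for genes called whichever array was left out.

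The fits were tested on simulated data. For radiation over both hosts, 86% of 100 genes changed 2-fold and 100% of 100 changed 4-fold were recovered, with 12 false calls among 11345 genes. That simulation drew the spread between pools from the prior that limma had fitted and gave duplicates no noise. It therefore checks the fit under its own assumptions only. For radiation in WT, 51% and 97% were recovered with 2 false calls, and for the difference between radiation effects 49% and 92% with 6. The latter 2 simulations hold only the spread between duplicate arrays, so their false calls cover array noise and no variation between pools or animals. Camera found a shifted list and called 0 of 20 unshifted ones. The simulated genes were drawn independently, so this does not cover false calls on lists whose genes move together.

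Alternatives were quantile normalization, arrays centred on the median, other pseudocounts (none, 64), no filter or a filter at the 75th percentile, the mean of a gene's probe sets, other fold thresholds, the limma-trend fit, 8-array fits with and without the replicate number as a block, and leaving out each array in turn. After the data were seen, fits on the pools of 1 host or 1 treatment and an estimated correlation on the 8-array additive fit were added. Splits of the samples into other groups were not counted, as no group holds 3 samples.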

Results

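B16F1 mouse melanoma cells were grown under the skin of the hind limb in wild-type C57BL/6 mice (WT) or in mice lacking both TNF receptors (TNFR KO). Tumours were left untreated or received 20 Gy of X-rays and were excised 5 h afterwards. RNA of whole tumours was combined into 1 pool per group, and each of the 4 pools was measured on 2 Affymetrix whole-genome mouse arrays. The series asks which genes accompany the greater radiation sensitivity of these tumours when the host tissue cannot respond to TNF. Signals are given as the mean ± SD of the 2 arrays of a pool (n = 2 technical duplicates), and log2 differences with the standard error of limma. Duplicate arrays correlated at 0.975 to 0.981 across probe sets, pools of the same host at 0.971 to 0.972 and pools of different hosts at 0.955 to 0.964.

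Tnfrsf1a, which encodes TNF receptor 1, was read in every pool, at 2702 ± 70.3 (WT untreated), 3874 ± 82.7 (WT irradiated), 3409 ± 184 (TNFR KO untreated) and 4196 ± 203 (TNFR KO irradiated). The tumour cells carry receptor genes of their own in every host, and whether the probe sets lie in the disrupted part of either gene is not known here. Over both treatments its host difference was 0.22 ± 0.16 (adjusted p = 0.314). Tnfrsf1b, which encodes TNF receptor 2, read 191 ± 47.9 and 416 ± 50.3 in the WT pools and 127 ± 0.212 and 128 ± 27.6 in the TNFR KO pools, untreated and irradiated. It was 2.08-fold lower in TNFR KO hosts (log2 difference -1.06 ± 0.23, adjusted p = 0.00708). The call was lost without TNFR KO irradiated replicate 2 (log2 difference -1.15), without WT untreated replicate 1 (-0.94) and without WT irradiated replicate 1 (-0.996). A second, dimmer probe set of Tnfrsf1b was also lower untreated (-0.98) but not irradiated (0.49), at -0.25 over both treatments. Tnf itself read between 13.8 and 22.6 in the 4 pools, below the level tested.

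Controls added to the RNA before labelling separated the hosts. The poly-A spike-in transcripts dap, lys, phe and thr averaged 18207, 2990.3, 5423 and 6848 on the 4 WT arrays and 11.5, 21.8, 11.7 and 17.7 on the 4 TNFR KO arrays. Hybridisation controls, which enter later, were alike, with bioB at 704 and 676 and cre at 24014 and 23520. Probe sets for 18S ribosomal RNA averaged 316 in WT and 736 in TNFR KO, and the irradiated arrays read 1.16 times the untreated ones in WT and 1.79 times in TNFR KO. The 5' to 3' ratio of actin, a measure of RNA integrity, was 0.786 and 0.731 in the untreated and irradiated WT pools and 0.794 and 0.797 in the TNFR KO pools. Host and target preparation therefore cannot be told apart in any comparison between hosts, whereas each radiation comparison lies within 1 host. The 18S signal, however, moved with radiation and by a different factor in each host. Within WT the irradiated arrays also read 1.61 to 2.11 times the untreated ones for the spike-ins, against 1.19 to 1.26 times for the hybridisation controls. A difference in RNA or preparation within hosts is therefore not excluded.

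**Figure D1:**
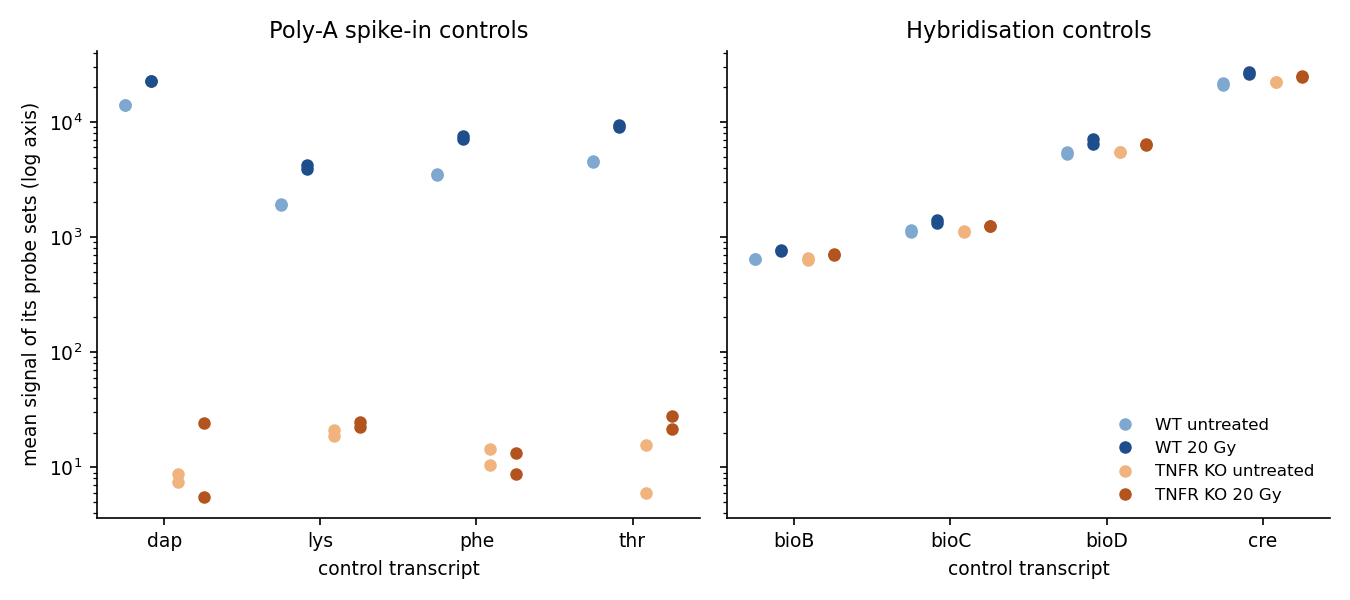
Mean signal (log axis) of the probe sets of each poly-A spike-in and each hybridisation control, 1 point per array, coloured by pool. The spike-ins lie above 1897 on all 4 WT arrays and below 28 on all 4 TNFR KO arrays, while the hybridisation controls overlap.

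What 20 Gy changed in tumours of both hosts was examined first. At 5 h, 14 of 19 p53 targets, 7 of 15 immediate-early genes and 3 of 13 heat shock genes passed as higher, and 6 of 24 mitotic and 6 of 11 skeletal muscle genes as lower. Cdkn1a, the cell-cycle inhibitor p21, went from 4997 ± 9.19 to 19252 ± 298 in WT hosts and from 5549 ± 98.6 to 19219.6 ± 734 in TNFR KO hosts, a 3.64-fold rise (log2 difference 1.87 ± 0.16, adjusted p = 0.00032). Hspa1b, which encodes an inducible Hsp70, rose 6.68-fold (adjusted p = 5.11e-05), from 2175 to 13447 in WT and from 1454 to 10654 in TNFR KO hosts.

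Of 19 p53 target genes tested, 14 rose and none fell (17 rose when adjusted over the list alone). Beside Cdkn1a these included the negative regulator of p53 Mdm2 (log2 difference 0.97 ± 0.21), the cyclin G1 gene Ccng1 (1.64 ± 0.20), Trp53inp1 (2.09 ± 0.18, and 0.83 on its other bright probe set), the antiproliferative factor Btg2 (1.98 ± 0.18) and Sesn2 (1.79 ± 0.17). As a list they moved up relative to other genes (adjusted p = 4.75e-23 in camera, limma's competitive test of gene lists; adjusted p = 0.615 with an estimated correlation from the pools). Immediate-early genes, which respond to stimuli without new protein synthesis, showed 7 of 15 higher (10 higher and 1 lower adjusted over the list alone; adjusted p = 1.2e-09; adjusted p = 0.615 with an estimated correlation). Fos rose by 1.33 ± 0.24, Atf3 by 1.68 ± 0.28 and Ccn1 by 1.33 ± 0.16 on the log2 scale. These values average the hosts, and Fos and Atf3 rose unequally in them. On the arrays of replicate 1, Fos went from 2992 to 5239 in WT and from 1554 to 5975 in TNFR KO hosts. Atf3 went from 423 to 2452 and from 621 to 1216. Fosb, dim without irradiation, went from 30.4 to 243 in WT and from 52.7 to 402 in TNFR KO hosts (log2 difference 2.99 with no pseudocount and 1.85 with 64).

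Among 13 heat shock and unfolded protein response genes, 3 rose, over all genes and adjusted over the list alone: Hspa1b, Hspa1a (2.06 ± 0.16) and the Hsp40 gene Dnajb1 (1.18 ± 0.17). The list gave adjusted p = 0.00206, and adjusted p = 0.759 with an estimated correlation, with a list median of 0.05. Hspa1a and Hspa1b are nearly identical in sequence, so their probe sets may not separate them. Hspb1, the small heat shock protein Hsp27, rose by 2.52 ± 0.16.

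Of 24 mitotic genes tested, 6 fell and 18 did not pass, while 18 passed as lower when adjusted over the list alone (adjusted p = 5.67e-14; adjusted p = 0.615 with an estimated correlation). The log2 difference was -0.92 ± 0.16 for the mitotic kinesin Kif20a, -0.82 ± 0.16 for the centrosome kinase Nek2 and -1.03 ± 0.18 for the spindle gene Hmmr, whose 4 other bright probe sets differed by -0.72 to -0.37. Of 11 skeletal muscle genes 6 fell, 10 when adjusted over the list alone (adjusted p = 1.15e-12; adjusted p = 0.615 with an estimated correlation). The fast myosin gene Myh1 went from 321 to 73.2 in WT and from 238 to 28.3 in TNFR KO hosts, and the skeletal actin gene Acta1 from 1605 to 404 and from 522 to 238. With the correlation estimated on all 8 arrays, a test added after the data were seen, 4 lists passed: p53 targets (adjusted p = 0.0287), mitosis (adjusted p = 0.00809), skeletal muscle (adjusted p = 0.0287) and immediate-early genes (adjusted p = 0.0287). That fit counts duplicate arrays as replicates, so its p-values overstate the evidence from 4 pools.

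Transcripts of other cell types moved after irradiation. Erythroid transcripts were higher after irradiation, with 2 of 3 tested genes called and 3 adjusted over the list alone. Alas2, the erythroid enzyme of haem synthesis, went from 326 ± 35.2 to 1364 ± 57.1 in WT and from 397 ± 21.4 to 3574 ± 211 in TNFR KO hosts. Hbb-b2, an adult beta-globin gene with near-identical relatives, went from 133 to 405 in WT and from 50.9 to 757 in TNFR KO hosts (log2 difference 2.78 with no pseudocount and 2.05 with 64, the call lost with none), whereas its second bright probe set differed by -0.19. The keratins Krt6b and Krt6a were lower, from a high level in the untreated TNFR KO pool: from 995 to 57.5 and from 439 to 138. The call on Krt6b ended whichever array was left out (log2 differences of -2.69 to -2.35). The keratinocyte list did not follow as a whole: 0 of 3 tested genes were called by limma, over all genes or adjusted over the list alone, with medians of 0.81 in WT and -1.30 in TNFR KO hosts. Car3, a carbonic anhydrase of muscle and fat, went from 207 to 46.1 in WT and from 118 to 25.6 in TNFR KO hosts (log2 difference -2.18 with no pseudocount and -1.16 with 64), and Klf15 fell by 1.21 ± 0.22.

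In the pool-level limma fit, 176 of 11345 tested genes were higher and 40 lower after irradiation, and 1889 had an unadjusted p under 0.05. Its error is the difference between the radiation effects of the 2 hosts, not a spread between replicate pools. Between independent pools the same direction returned: 55 genes were called higher in both hosts (2.25 by chance if calls were independent), 5 lower in both (0.112 by chance) and 6 in opposite directions (1.44 by chance). Across genes the differences in the 2 hosts correlated with Pearson's r of 0.37 and Spearman's rho of 0.35, genes not being independent replicates. The pool-level calls rest on every array: the count of higher genes was 0 without WT untreated replicate 1, where 1555 had an unadjusted p under 0.05 in limma, and 11 without WT untreated replicate 2. It was 3 and 100 without WT irradiated replicates 1 and 2, 42 and 48 without TNFR KO untreated replicates 1 and 2, and 61 and 17 without TNFR KO irradiated replicates 1 and 2; quantile normalization left 2 higher and 0 lower (100% higher against 81.5%).

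**Figure D2:**
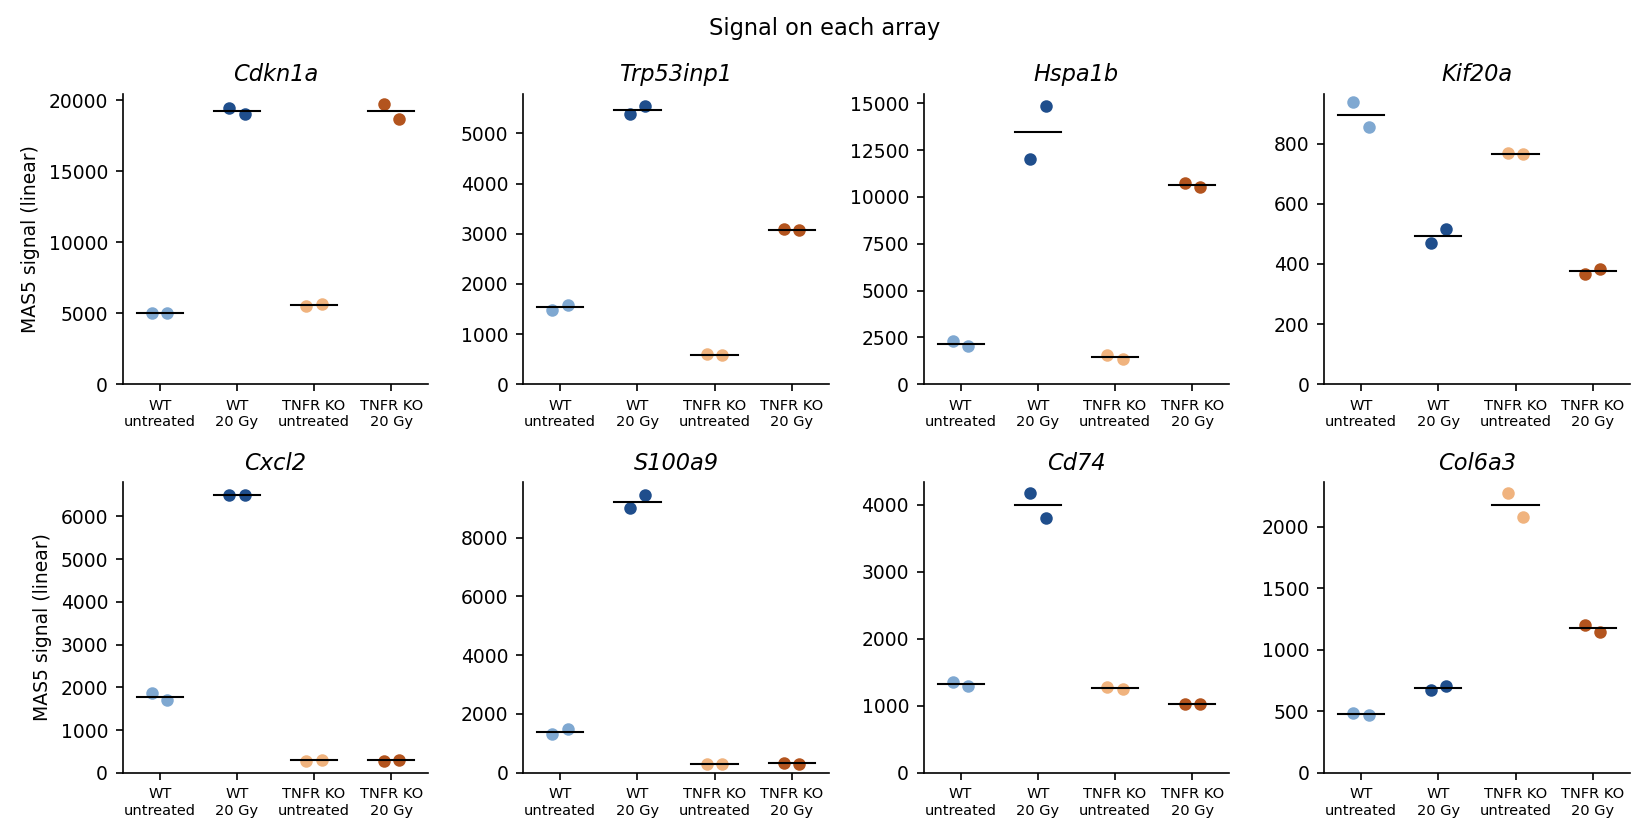
MAS5 signal (linear scale) of 8 genes on each array (points) and the pool mean (bars) for WT and TNFR KO hosts, untreated and 20 Gy. Cdkn1a, Trp53inp1 and Hspa1b are higher and Kif20a lower in both irradiated pools, whereas Cxcl2, S100a9 and Cd74 are highest in the irradiated WT pool and Col6a3 in the untreated TNFR KO pool.

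Tumours of the 2 hosts were then compared over both treatments. Several chemokine and neutrophil transcripts were far lower in tumours of TNFR KO hosts, while TNF and NF-kB targets as a list were not, and many matrix and vessel transcripts were higher. Lcn2, an iron-binding protein of neutrophils and the acute phase, read 1688 ± 10.2 and 4435 ± 142 in the WT pools against 229.8 ± 34.2 and 105 ± 24.7 in the TNFR KO pools, untreated and irradiated, a 16.1-fold difference (adjusted p = 0.000245). The neutrophil attractant Cxcl2 read 1779 ± 114 and 6494 ± 0.424 against 294 ± 14.4 and 294 ± 19.1 (11-fold lower, adjusted p = 0.000241). All of these values carry the difference in spike-in controls between the hosts' arrays.

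The calprotectin subunits S100a9 (log2 difference -3.48 ± 0.43) and S100a8 (-3.29 ± 0.41; its probe set may also read related sequences) led the neutrophil markers, of which 4 of 5 were lower and none higher (5 lower adjusted over the list alone; adjusted p = 0.0053; adjusted p = 0.889 with an estimated correlation). The chemokine genes Ccl3 (-3.26 ± 0.39) and Cxcl3 (-3.10 ± 0.36), the itaconate enzyme Acod1 (145 and 520.3 in WT against 23.1 and 7 in TNFR KO hosts, untreated and irradiated) and the pattern receptor Clec4e (131 and 711 against 41.4 and 40.0; log2 difference -2.91 with no pseudocount and -1.89 with 64) were among the 12 lowest. TNF and NF-kB targets went both ways: 4 of 22 were higher and 5 lower, over all genes and adjusted over the list alone, and the list over both treatments did not shift (adjusted p = 0.5). That value averages opposite medians, 0.47 untreated (3 higher and 2 lower) and -0.70 irradiated (0 higher and 9 lower). Interferon-response genes were lower, 16 of 36 against 2 higher, with the same counts adjusted over the list alone (adjusted p = 0.000477; adjusted p = 0.889 with an estimated correlation). The interferon-induced GTPases Iigp1 (-2.23 ± 0.22) and Gbp2 (-2.02 ± 0.30) and the antiviral gene Ifit1 (-1.69 ± 0.27) were examples, with relatives of similar sequence. Of 13 antigen presentation genes 6 were lower, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.0794); the median was 0.023 untreated (1 higher) and -1.20 irradiated (7 lower). Interferon and neutrophil medians were -0.26 and -0.23 untreated, and -0.84 and -1.28 irradiated. Macrophage markers had 1 of 22 lower, Arg1, none adjusted over the list alone (adjusted p = 0.618); their median was 0.75 untreated (7 higher) and -0.51 irradiated (5 lower). The call on Arg1 ended without TNFR KO untreated replicate 1 or 2 (-0.78, -0.81), TNFR KO irradiated replicate 1 or 2 (-0.76, -0.83), WT untreated replicate 1 or 2 (-0.79, -0.79) or WT irradiated replicate 1 (-0.80).

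Fibroblast and matrix genes were higher, 14 of 20 against 1 lower (15 and 1 adjusted over the list alone; adjusted p = 4.95e-05; adjusted p = 0.889 with an estimated correlation). The collagen VI genes Col6a1 (log2 difference 1.51 ± 0.24) and Col6a3 (1.46 ± 0.27) and the growth factor receptor gene Pdgfrb (1.32 ± 0.17, and 0.59 on its other bright probe set) were the clearest. Outside the list, Col12a1 and Lrrc15 were higher as well, from WT signals below the level for testing (log2 differences of 1.90 with no pseudocount and 1.08 with 64, and of 1.82 with no pseudocount and 1.11 with 64). Endothelial markers showed 7 of 17 higher and none lower (8 adjusted over the list alone; adjusted p = 0.00114; adjusted p = 0.889 with an estimated correlation), among them Esam (1.07 ± 0.18), Sox18 (0.99 ± 0.16) and Tie1 (0.94 ± 0.16). The apelin receptor gene Aplnr, read in vessels, differed by 1.68 ± 0.16. Most of this lay in the untreated pools, with matrix medians of 1.45 untreated (14 higher, 0 lower) and 0.58 irradiated (2 higher, 2 lower), and endothelial medians of 0.77 (6 higher) and 0.33 (0 called by limma at 2-fold against duplicate arrays). Smooth muscle and pericyte genes had 3 of 8 higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.114), with Acta2 at 0.87 ± 0.16.

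Other tissue moved with the host too. Keratin and cornified-layer genes were highest in the untreated TNFR KO pool, where Krt6b read 995 ± 49.9 against 41.1 ± 17.2 in untreated WT, and 3 of 3 tested keratinocyte genes were higher, also adjusted over the list alone. In the irradiated pools 0 of the 3 were called by limma against duplicate arrays. All 3 calls (Krt5, Sprr1a and Lor) ended without any 1 of 6 arrays, with log2 differences of 1.52, 1.11 and 0.81 without TNFR KO untreated replicate 1; 1.13, 1.03 and 0.77 without TNFR KO untreated replicate 2; 1.48, 0.98 and 0.75 without TNFR KO irradiated replicate 2; 1.77, 1.03 and 0.78 without WT untreated replicate 1; 0.88, 1.11 and 0.80 without WT untreated replicate 2; 1.18, 1.05 and 0.74 without WT irradiated replicate 1. The call on Krt5 also ended without TNFR KO irradiated replicate 1 (1.17). Skeletal muscle genes were lower in TNFR KO hosts, 8 of 11 (9 adjusted over the list alone; adjusted p = 0.000134; adjusted p = 0.889 with an estimated correlation), as for Myl1 and Tnni2. Both were below the level for testing in the irradiated TNFR KO pool, and their log2 differences were -2.09 with no pseudocount and -0.99 with 64, and -1.57 with no pseudocount and -0.74 with 64. Erythroid genes were higher, 2 of 3 tested, also adjusted over the list alone: Slc4a1 (1.28 ± 0.23) and Alas2 (0.83 ± 0.23). In the untreated pools 0 were called higher by limma and 1 lower (median 0.27), and in the irradiated pools 2 higher (median 1.38). The call on Alas2 ended without TNFR KO untreated replicate 1 or 2 (0.85, 0.80), TNFR KO irradiated replicate 1 or 2 (0.86, 0.80), WT untreated replicate 1 or 2 (0.88, 0.77) or WT irradiated replicate 1 (0.81).

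Cell-cycle and repair genes were divided. Of 24 mitotic genes 8 were lower, with the same count adjusted over the list alone (adjusted p = 0.161), led by the checkpoint kinase gene Bub1 (-1.59 ± 0.16) and Mki67 (-1.42 ± 0.24). Another bright probe set of Bub1 differed by -0.58. The condensin gene Smc4 differed by -2.17 ± 0.18 and Zfp386 by -2.21 ± 0.16. Of 23 replication genes 8 were higher and 1 lower (10 and 2 adjusted over the list alone; adjusted p = 0.157), and of 22 repair genes 3 were higher and 8 lower (3 and 10 adjusted over the list alone; adjusted p = 0.114). The end-joining ligase Lig4 (-1.63 ± 0.17) and the checkpoint kinase Atr (-1.02 ± 0.17) were lower, and Xrcc3 (1.13 ± 0.17) higher. Among p53 targets 1 of 19 was higher and 5 lower, also adjusted over the list alone (adjusted p = 0.571), with Ccng1 at -1.51 ± 0.20.

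The pool-level limma fit called 1364 genes higher and 2140 lower in TNFR KO hosts, 30.9% of those tested, of which 91 and 722 differed at least 2-fold. Arrays centred on their median gave 1849 and 1788 (50.8% higher against 38.9%), and with no filter on dim probe sets limma called 0, with 4487 at an unadjusted p under 0.05. The count of higher genes fell to 500 and 644 without WT untreated replicates 1 and 2, to 591 without WT irradiated replicate 1, to 727 and 833 without TNFR KO untreated replicates 1 and 2, and to 803 and 696 without TNFR KO irradiated replicates 1 and 2.

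Host differences were also read at each treatment, where a single pool stands on each side and p-values measure only the spread between duplicate arrays of the same RNA. Without irradiation 234 genes were at least 2-fold higher and 709 lower in the TNFR KO pool, and after irradiation 90 and 843 (167 and 657 with arrays centred on their median, 20.3% against 9.65% higher; 140 higher without WT irradiated replicate 1). Among the 5 highest untreated differences, Krt6b read 995 in the TNFR KO and 41.1 in the WT pool, the epidermal gene Dmkn 309.6 and 34, Rhbdf2 387 and 53, and Urah 319.6 and 41. Among the 5 lowest were Lcn2 (log2 difference -2.80), Cxcl2 (-2.53), the tRNA-modifying enzyme gene Alkbh8 (-2.19) and Zfp958, at 16.6 against 150.1. After irradiation Lcn2 (-5.22), S100a9 (-4.79) and Ccl3 (-4.42) were lower, as was Acod1, at 7 against 520.3. The red cell anion exchanger Slc4a1 (1.80) and Mroh2a, at 119 against 17.3, were higher. Where only signals are given, 1 side lies below 68.8, the level for testing, and the size and order of the log2 differences depend on the pseudocount. The comparisons share no pool: 20 genes were higher in both (1.86 by chance), 487 lower in both (52.7 by chance) and 2 opposite (23.0 by chance), with Pearson's r of 0.72 and Spearman's rho of 0.69 across genes. Both comparisons, however, set arrays with spike-in signal against arrays without it. A difference in target preparation between the hosts could give this agreement too, so it does not separate host from preparation.

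Whether radiation acted differently in the 2 hosts bears most directly on the question of the series. In the WT pools 14 of 22 TNF and NF-kB targets, 4 of 5 neutrophil, 7 of 22 macrophage and 8 of 13 antigen presentation genes were higher after irradiation; in the TNFR KO pools 0, 0, 0 and 1 were, while 4 TNF and NF-kB targets and 2 macrophage genes were lower. The differences between these effects were tested directly. S100a9 went from 1404 ± 104 to 9222 ± 302 in WT and from 297 ± 7.78 to 318 ± 23.2 in TNFR KO hosts, a difference between the radiation effects of -2.61 ± 0.12 on the log2 scale (adjusted p = 0.000943). Cd74, the chaperone of class II antigen presentation, went from 1322 ± 46 to 3992 ± 269 in WT and from 1265 ± 26.1 to 1027 ± 4.31 in TNFR KO hosts (-1.88 ± 0.10, adjusted p = 0.00172). The p53 response, in contrast, was present in both hosts, with list medians of 1.23 in WT and 1.36 in TNFR KO hosts. Cdkn1a differed by -0.15 ± 0.081 (adjusted p = 0.269). Its list was not equal throughout, with differences of -0.49 to 0.83 and a median of 0.30, and Ccng1 at 0.81.

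Of 22 TNF and NF-kB targets, 15 had a lower radiation effect in TNFR KO hosts and none a higher one (17 adjusted over the list alone; adjusted p = 5.16e-14; adjusted p = 0.00764 with an estimated correlation). Here, as for every list of this difference, the correlation was estimated from duplicate arrays and covers array noise only. The median log2 effect of TNF and NF-kB targets was 1.14 in WT and -0.16 in TNFR KO hosts. The interleukin gene Il1b (-2.23), the acute-phase gene Saa3 (-2.62) and Cxcl2 (-1.86) were among them. Macrophage markers had 19 of 22 lower (21 adjusted over the list alone; adjusted p = 3.76e-20; adjusted p = 0.00764 with an estimated correlation), with medians of 0.89 and -0.40. Csf1r, the receptor for the macrophage growth factor, went from 789 to 1251 in WT and from 2431 to 1198 in TNFR KO hosts. The macrophage list thus started higher in the untreated TNFR KO pool, by a median of 0.75 over untreated WT. Interferon-response genes had 9 of 36 lower (24 adjusted over the list alone; adjusted p = 3.22e-12; adjusted p = 0.00764 with an estimated correlation), antigen presentation 6 of 13 (12; adjusted p = 5.23e-12; adjusted p = 0.0271 with an estimated correlation) and neutrophil markers 2 of 5 (4; adjusted p = 0.000123; adjusted p = 0.0416 with an estimated correlation), the counts in parentheses again adjusted over the list alone.

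Stromal genes differed as well, from the high level of the untreated TNFR KO pool in which keratin genes were also high. Fibroblast and matrix genes had 10 of 20 lower (16 adjusted over the list alone; adjusted p = 3.43e-12; adjusted p = 0.0137 with an estimated correlation). Col6a3 went from 478 to 688 in WT and from 2176 to 1178 in TNFR KO hosts. Endothelial markers had 2 of 17 lower (8 adjusted over the list alone; adjusted p = 0.0016; adjusted p = 0.0505 with an estimated correlation). Replication genes differed the other way, 1 of 23 higher (13 adjusted over the list alone; adjusted p = 1.75e-06; adjusted p = 0.025 with an estimated correlation), with medians of -0.31 in WT and 0.14 in TNFR KO hosts. Erythroid genes also differed upwards, 3 of 3 over all genes and adjusted over the list alone, with a median of 1.10, and adipocyte genes downwards, 2 of 4 in both adjustments. Keratinocyte genes differed downwards as well, 1 of 3 over all genes and 3 adjusted over the list alone, with a median of -1.43. No p53 target passed alone over all genes (5 higher adjusted over the list alone; adjusted p = 0.0246; adjusted p = 0.227 with an estimated correlation). Mitotic genes (adjusted p = 0.878), skeletal muscle (adjusted p = 0.553) and melanocyte genes (adjusted p = 0.548) did not differ as lists.

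The array-level limma fit called 18 genes with a higher and 233 with a lower radiation effect in TNFR KO hosts, at least 2-fold, from 255 higher and 23 lower in WT hosts and 100 and 55 in TNFR KO hosts. With a single pool per group these p-values set differences between pools against the spread between duplicate arrays, not between animals. The 18 became 6 without WT untreated replicate 1 and 8 without TNFR KO untreated replicate 1 or TNFR KO irradiated replicate 2, the 233 became 155 and 148 without TNFR KO untreated replicates 1 and 2, and the 23 became 42 without WT irradiated replicate 2.

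**Figure D3:**
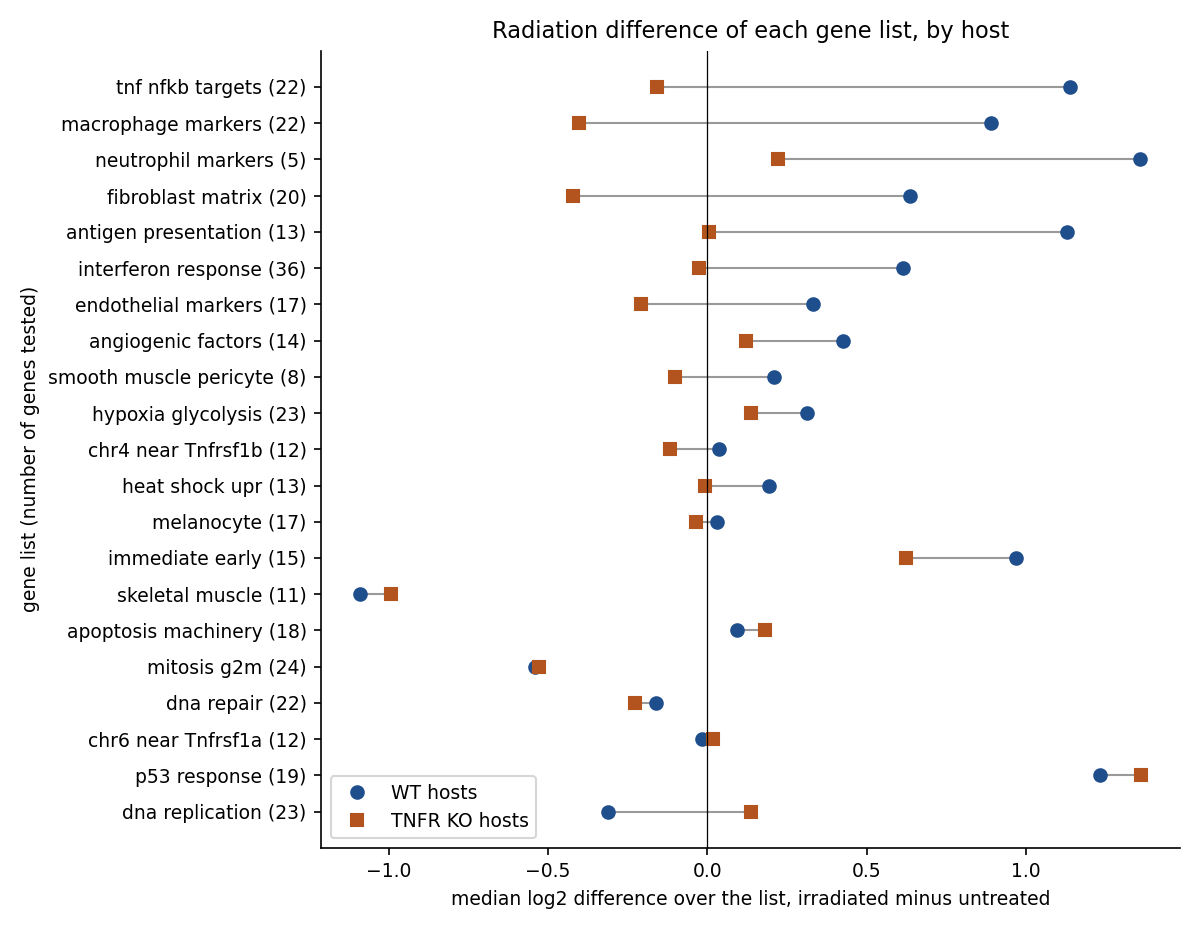
Median log2 difference, irradiated minus untreated, of each gene list with at least 5 tested genes, in WT hosts (circles) and TNFR KO hosts (squares). TNF target genes lie at 1.14 in WT and -0.16 in TNFR KO hosts, whereas p53 targets lie at 1.23 and 1.36.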

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

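The tests of an array offset, of the stromal and macrophage shares and of the muscle content were chosen only after the results they address were seen.

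Spike-in transcripts, which enter no comparison of genes, were present on the arrays of a single host. On the 4 WT arrays dap averaged 18207, lys 2990.3, phe 5423 and thr 6848; on the 4 TNFR KO arrays they averaged 11.5, 21.8, 11.7 and 17.7. Within WT hosts the irradiated arrays read 1.61, 2.11, 2.10 and 2.03 times the untreated ones for the same 4 controls.

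Several of the 3504 host differences could come from target preparation, since poly-A controls were read only on the WT arrays, and preparation and host cannot be told apart in this design. A test set beforehand compared how far the 2 brightest probe sets of a gene moved together: the common share of their variance was 0.725 between hosts and 0.602 after irradiation, a difference of 0.123 (95% bootstrap interval 0.0878 to 0.16 over 5183 genes, 1000 resamples). That criterion would have excluded preparation as the whole cause, but on seeing the value it was judged unfit and preparation was left open: a share of this kind rises with the size of the differences, and these had an SD of 0.56 between hosts against 0.29 after irradiation. Array scaling as the whole cause was argued against, since 74.2% of the called genes stayed called in the same direction after quantile normalization. The absent host receptors, the mixed 129 origin of the TNFR KO line and the tissue taken with each tumour stay open, untested.

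The radiation effect differed between hosts by the test of the difference itself for 18 genes that were higher and 233 that were lower in TNFR KO than in WT hosts. By gene, the differences were 2.00 for Hbb-b2, 1.96 for Cpne5, 1.45 for Snorc, 1.42 for Plekha7 and 1.35 for Fbrsl1, and -2.83 for Chil3, -2.68 for Fpr2, -2.62 for Saa3, -2.61 for S100a9 and -2.60 for Krt6b. The size and order of several depend on the pseudocount, since a pool read below 68.8, the level for testing: Hbb-b2 (50.9), Snorc (33.2), Chil3 (28.1), Fpr2 (54.6) and Krt6b (8.0). With a pseudocount of 64 they were 1.55, 0.89 with the call lost, -1.92, -2.09 and -2.60. Other probe sets of Hbb-b2 (0.041) and Fbrsl1 (-0.14 to 0.49) did not follow. Each of the calls on Hbb-b2, Cpne5, Snorc, Plekha7, Fbrsl1, Fpr2 and Krt6b was lost in at least 4 of the 8 fits that left out 1 array; the 18 became 6 without WT untreated replicate 1.

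By list, the median differences were -1.44 for TNF and NF-kB targets, -1.39 for macrophage markers, -1.14 for neutrophil markers, -1.06 for fibroblast and matrix genes, -0.92 for antigen presentation and -0.66 for interferon response. They were -0.48 for endothelial markers, -0.44 for angiogenic factors, -0.24 for hypoxia and glycolysis, -0.21 for heat shock, 0.43 for replication and 0.30 for p53 targets. The last 6 except replication were lost with an estimated correlation (adjusted p from 0.0505 to 0.227).

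The different radiation response of TNF targets and neutrophil markers may reflect which cells the pools held. An offset between the hosts' arrays that is equal on the log scale at both treatments cancels in this difference by arithmetic, so it leaves the median of -1.42 over the 27 tested genes, all negative, unaccounted for. An offset that changed with treatment was not tested and stays open, as 18S ribosomal RNA on irradiated arrays read 1.79 times the untreated level in TNFR KO and 1.16 times in WT hosts. The spike-ins, present on WT arrays only, read 1.61 to 2.11 times their untreated level on the irradiated WT arrays. Macrophage markers lay below endothelial markers by a median of -0.91 (95% interval -1.45 to -0.46, genes resampled), so the 2 lists did not shift equally. Resampled genes hold no spread between pools, so this does not decide whether the share of stromal cells as a whole differed. In the untreated pools the host differences of the 2 lists were alike, with medians of 0.75 and 0.77. Fibroblast and matrix genes lay nearer the macrophage markers, with a median of -1.06 and 19 of 20 negative. Medians were -1.43 for 3 keratinocyte and -0.98 for 4 adipocyte genes, against -0.40 for 8 smooth muscle and -0.17 for 3 lymphocyte genes. A shift shared by stromal cells, or by macrophages and fibroblasts alone, therefore stays open. A different share of macrophages stays open: the 27 genes differed from the macrophage markers by only -0.028 (interval -0.43 to 0.47), and the abundant macrophage gene Lyz2 went from 2044 to 3143 in WT and from 3848 to 2283 in TNFR KO hosts. Absence of TNF signalling in host cells is the explanation the design names, and it was not tested apart from cell content, since each group was 1 pool.

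Muscle transcripts were lower after irradiation in both hosts, 10 of 11 tested genes by direction. A smaller amount of limb muscle in the irradiated pools stays open: that count was made on the genes that prompted it, and a direct effect would give it too, so it decides nothing. Acta1, the most abundant of them in untreated WT, went from 1605 to 404 in WT hosts, and the log2 differences over both hosts ranged from -2.22 to -0.059. A direct effect of 20 Gy on muscle transcripts was not tested and stays open.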

How the results depend on the processing

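The fits limited to the pools of 1 host or 1 treatment, and the estimated correlation on the 8-array additive fit, were tests chosen only after the data were seen. The causes of the changes below were not tested unless stated.

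Leaving out each array in turn lowered the pool-level counts. Host differences ranged from 500 to 983 genes higher (1364 with all arrays) and from 1534 to 1921 lower. Radiation differences ranged from 0 to 100 higher and from 0 to 17 lower, and were 0 without WT untreated replicate 1, where the prior degrees of freedom of limma dropped from 9.52 to 3.98 and 1555 genes had an unadjusted p under 0.05. The lower genes numbered 4 and 4 without TNFR KO untreated replicates 1 and 2, 5 and 2 without TNFR KO irradiated replicates 1 and 2, 2 without WT untreated replicate 2, and 0 and 17 without WT irradiated replicates 1 and 2.

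Array-level counts moved less. In the untreated host comparison 210 to 290 genes were higher and 671 to 732 lower, and in the irradiated one 88 to 140 and 824 to 902, the 140 without WT irradiated replicate 1. Radiation gave 213 to 259 and 20 to 42 in WT hosts, the 42 without WT irradiated replicate 2, and 92 to 112 and 38 to 73 in TNFR KO hosts. The difference between radiation effects gave 6 to 20 and 148 to 189, with 6 without WT untreated replicate 1, 8 without TNFR KO untreated replicate 1 or TNFR KO irradiated replicate 2, and 155 and 148 lower without TNFR KO untreated replicates 1 and 2. Host differences shared by both treatments ranged from 16 to 26 higher and 460 to 490 lower, and radiation differences shared by both hosts from 49 to 57 higher and 3 to 6 lower, the 3 without TNFR KO untreated replicate 1. Lists called numbered 5 to 5 between hosts, 12 to 13 after irradiation and 10 to 13 for the difference. Of 1832 tests of a named gene without 1 array, 503 lost the call and 0 changed direction.

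Scaling mattered for the pool-level count of radiation differences. Quantile normalization left 2 genes higher and 0 lower after irradiation over both hosts, with 1508 at an unadjusted p under 0.05 in limma. The prior degrees of freedom were then 4.11 against 9.52. Within hosts the counts moved little, with 223 against 255 genes higher in WT, 107 against 100 in TNFR KO and 53 against 55 in both. The same scaling gave 172 higher in irradiated TNFR KO against WT and 32 with a higher radiation effect in TNFR KO hosts. Centring on the median gave 94 and 10 after irradiation, 167 higher in the irradiated host comparison and 31 higher in both host comparisons.

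Without a pseudocount 74 genes were higher and 10 lower after irradiation over both hosts. With a pseudocount of 64 these were 340 and 170, with 133 and 35 genes higher in the untreated and irradiated host comparisons, 164 higher and 10 lower after irradiation in WT, 25 lower in TNFR KO and 7 with a higher radiation effect. Shared differences fell to 6 higher between hosts and 2 lower after irradiation.

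With no filter limma called 0 genes in either direction for host and for radiation, with 4487 and 1998 of 18193 at an unadjusted p under 0.05 and 3.93 prior degrees of freedom, while 370 and 178 were higher in the untreated and irradiated host comparisons and 3 lower in both hosts after irradiation. A filter at the 75th percentile gave 155 lower after irradiation, 91 and 406 in the untreated and 39 and 447 in the irradiated host comparison, 97 and 7 after irradiation in WT, 57 and 15 in TNFR KO, and 9 and 89 for the difference. Shared differences were 7 and 294 between hosts and 33 and 2 after irradiation. Taking the mean of a gene's probe sets gave 271 higher after irradiation, 407 and 514 lower in the untreated and irradiated host comparisons, 12 and 31 lower after irradiation in WT and TNFR KO, and 244 lower between hosts and 2 lower after irradiation among shared differences.

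Thresholds moved counts as such. With no fold threshold the untreated host comparison had 2998 higher and 2698 lower, the irradiated one 3223 and 3093, radiation 1378 and 1516 in WT and 1070 and 1631 in TNFR KO, the difference 399 and 685, and shared differences 1893 and 2214 between hosts and 429 and 556 after irradiation. At 1.5-fold these were 1027 and 1703, 948 and 1994, 628 and 249, 337 and 423, 164 and 483, 302 and 1344, and 145 and 60. A 2-fold threshold on the pool-level fits left 91 and 722 between hosts and 97 and 18 after irradiation.

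Other error models gave more pool-level calls. The robust limma-trend fit gave 2087 higher between hosts and 459 higher and 321 lower after irradiation. The 8-array additive fit, which counts duplicates as replicates, gave 3471 higher between hosts and 1062 and 1409 after irradiation. With replicate number as a block it gave 3234, 752 and 1019, and the block left 7 genes with a higher radiation effect in TNFR KO hosts. Replicate numbers do not pair arrays: deviations of replicate 1 correlated between pools at -0.0102 to 0.012.

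An estimated correlation between genes left 0 lists called between hosts, 0 after irradiation and 7 for the difference, and 0 and 4 on the 8-array additive fit. These counts are not comparable: the first 2 rest on 1 residual degree of freedom between pools, and the 7 on the spread between duplicate arrays, so the latter covers array noise only. The 4 lists come from the fit that counts duplicates as replicates. The p53 list lost its call for the difference with quantile normalization (adjusted p = 0.0525), no filter (0.0933) and the mean of probe sets (0.0738). It also lost it without TNFR KO untreated replicate 1 (0.0636), TNFR KO irradiated replicate 1 (0.0719), WT untreated replicate 2 (0.0518) and WT irradiated replicate 2 (0.0573). Heat shock genes lost theirs with the mean of probe sets (0.0738) and without TNFR KO untreated replicate 1 (0.0646) and WT untreated replicate 1 (0.06). At the 75th percentile endothelial markers (0.0825) and angiogenic factors (0.0717) lost theirs.

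Fits to the pools of 1 treatment or 1 host also take their error from duplicate arrays instead of pools, so their counts change for both reasons and were not separated. In the irradiated pools 3223 genes were higher between hosts, with Krt5 at -0.050 and Hbb-b2 at 0.85, both opposite in direction to the value over both treatments. In the untreated pools 2998 were, with Thbs1 at 0.33 and Atf3 at 0.42 reversed. For radiation the WT pools gave 1378 higher and 1516 lower and the TNFR KO pools 1070 and 1631. In the TNFR KO pools Cxcl9 (-0.55), Tyrobp (-0.32), Col5a2 (-0.59), Dcn (-0.74) and Birc3 (-0.69) had the direction opposite to that over both hosts.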

Other observations

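No test in this part was chosen only after a result was seen.

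Melanocyte lineage genes did not shift as a list. Of 17 melanocyte genes tested, none passed after irradiation, over all genes or adjusted over the list alone (adjusted p = 0.509). Between hosts 1 was higher and 2 lower, with the same counts adjusted over the list alone (adjusted p = 0.99). Mitf, the lineage transcription factor, read 12313 ± 365 and 8186 ± 399.5 in untreated and irradiated WT pools and 6009 ± 18.5 and 4886 ± 184 in TNFR KO pools (log2 host difference -0.89 ± 0.17, adjusted p = 0.00317). Its other bright probe set differed by only -0.27 between hosts. Angiogenic factors rose after irradiation in 3 of 14 genes (4 adjusted over the list alone; adjusted p = 0.000131; adjusted p = 0.759 with an estimated correlation): Ccn1, the placental growth factor gene Pgf (1.23 ± 0.21) and Ccn2 (0.90 ± 0.17), none of which passed without WT untreated replicate 1, when 0 genes did. Between hosts 3 of the 14 were higher, also adjusted over the list alone (adjusted p = 0.185), among them Pdgfb at 0.98 ± 0.18. The radiation effect on 2 of 14 was lower in TNFR KO hosts (7 adjusted over the list alone; adjusted p = 0.0053; adjusted p = 0.0684 with an estimated correlation).

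Hypoxia and glycolysis genes had no member past the test after irradiation (1 adjusted over the list alone), although the list moved up (adjusted p = 0.000764; adjusted p = 0.776 with an estimated correlation). Between hosts 4 of 23 were lower (2 adjusted over the list alone; adjusted p = 0.253), with the histone demethylase Kdm3a at -0.94 ± 0.16. In the difference of radiation effects none passed (8 lower adjusted over the list alone; adjusted p = 0.000193; adjusted p = 0.0505 with an estimated correlation). Repair genes moved down after irradiation as a list (adjusted p = 0.0105; adjusted p = 0.759 with an estimated correlation) with 0 of 22 past the test at the level of genes, and the differences between hosts in that effect did not pass (adjusted p = 0.548). Apoptosis genes had 0 of 18 past the test after irradiation (adjusted p = 0.103) and 1 higher and 4 lower between hosts (1 and 3 adjusted over the list alone; adjusted p = 0.311). The caspase inhibitor gene Xiap was at -0.91 ± 0.16, with 2 further probe sets at -0.66 and 0.096.

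Several inflammatory lists moved up in the fit over both hosts, but from the WT pools: in TNFR KO hosts the median radiation effect was -0.16 for TNF and NF-kB targets, -0.40 for macrophage markers, -0.027 for interferon response, 0.0037 for antigen presentation and 0.22 for neutrophil markers. TNF and NF-kB targets had 0 of 22 past the pool-level test (3 higher adjusted over the list alone; adjusted p = 0.000334; adjusted p = 0.778 with an estimated correlation), and macrophage markers 0 of 22 (adjusted p = 0.0179; adjusted p = 0.846 with an estimated correlation). Interferon-response genes had 1 of 36 higher (3 adjusted over the list alone; adjusted p = 6.77e-06; adjusted p = 0.776 with an estimated correlation), antigen presentation 1 of 13 (3; adjusted p = 6.77e-06; adjusted p = 0.776 with an estimated correlation) and neutrophil markers 1 of 5 (5; adjusted p = 4.76e-05; adjusted p = 0.759 with an estimated correlation). The 1 gene shared by the interferon and antigen lists was the peptide transporter Tap1, at 1.28 ± 0.17. Macrophage markers lost their call with arrays centred on the median (adjusted p = 0.0703) and without TNFR KO untreated replicate 2 (adjusted p = 0.0718).

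The remaining lists were small or did not pass in at least 1 comparison. Fibroblast and matrix (adjusted p = 0.208), endothelial (adjusted p = 0.791), smooth muscle (adjusted p = 0.375) and replication genes (adjusted p = 0.117) did not pass after irradiation over both hosts, where opposite medians in WT and TNFR KO hosts were averaged: 0.63 and -0.42 for matrix, 0.33 and -0.21 for endothelial, 0.21 and -0.10 for smooth muscle and -0.31 and 0.14 for replication genes. Immediate-early (adjusted p = 0.574) and heat shock genes (adjusted p = 0.38) did not pass between hosts. In the difference of radiation effects, smooth muscle (adjusted p = 0.34), immediate-early (adjusted p = 0.591) and apoptosis genes (adjusted p = 0.878) did not pass, and heat shock genes did (adjusted p = 0.0246; adjusted p = 0.116 with an estimated correlation). Lymphocyte markers were mostly too dim, with 3 of 20 tested and no gene called in either pool-level fit, and of 4 adipocyte genes 1, Car3, was lower in both comparisons (2 lower between hosts adjusted over the list alone). The host call on Car3 ended without TNFR KO untreated replicate 1 (-0.55).

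Genes that neighbour the targeted receptors were read because the TNFR KO line is in part of 129 origin. Near Tnfrsf1a 6 of 12 were higher in TNFR KO hosts (7 adjusted over the list alone; adjusted p = 0.0876), with Vwf at 0.83 ± 0.18 and Iffo1 at 0.68 ± 0.16. Near Tnfrsf1b 1 of 12 was higher, also adjusted over the list alone (adjusted p = 0.22). After irradiation neither set shifted (adjusted p = 0.953 and adjusted p = 0.956), nor did the radiation effects differ (adjusted p = 0.868 and adjusted p = 0.071). Of 3 tested genes that differ between 129 and C57BL/6 mice, 2 were lower in TNFR KO hosts: Trim30d (-0.98 ± 0.24) and Trim12a (-0.85 ± 0.24), both dim in the irradiated TNFR KO pool (with a pseudocount of 64 they were -0.63 and -0.56), calls that ended in 4 and 7 of the 8 fits that left out 1 array. Without WT untreated replicate 1 both ended, at -0.88 and -0.83; the call on Trim30d also ended without TNFR KO untreated replicate 1 (-0.93), TNFR KO irradiated replicate 2 (-1.07) and WT irradiated replicate 1 (-1.09), and the call on Trim12a stood only without WT irradiated replicate 2. Xist, the X-inactivation transcript, read 203 ± 15.8 and 408 ± 13.6 in the WT pools and 889 ± 19 and 619 ± 21.2 in the TNFR KO pools, untreated and irradiated, while Y-linked genes lay below the level tested. It was called higher in TNFR KO hosts (log2 difference 1.32, and 0.47 on its other bright probe set). Its radiation effect was called lower in TNFR KO than in WT hosts (-1.47). The cause of either difference was not tested.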
